A study of Arabidopsis thaliana with 12 samples.

How the data were processed

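Gene expression was measured in the aerial part of 10-day-old Arabidopsis thaliana seedlings of the Columbia wild type. They grew on agar medium with sucrose under 16 h of light and 8 h of dark, with lights on at 6am. Total RNA was labelled as biotin-cRNA after priming with oligo(dT) and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The 12 arrays used here fall into 4 groups by time of harvest: 6am (0 h after lights on), 12pm (6 h), 6pm (12 h) and 12am (18 h, in the dark), with 3 replicates each. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The series' design also names a CCA1-overexpressing line, and its protocol names polysomal RNA; neither was analysed here.

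The deposited values are log2 expression per probe set, made by the authors with GCRMA in R 3.1 and affy 1.42.3, per the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalizes between arrays and summarises the probes of a probe set. Which arrays were normalized together is not given in the sources used here. The lowest value was 2.1 and 29.3% of all values lay within 0.1 of it, so many dim transcripts share one floor. No detection call was used here, and differences against a time at the floor depend on where the floor lies. The number of arrays limits the precision, and arrays carry no read depth. The median over all non-control probe sets was between 5.90 and 6.03 on every array, as normalization between arrays would leave it, so a change in the total amount of messenger RNA cannot be read from these values.

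Gene names came from the platform's annotation table, joined by gene identifier to RefSeq gene names of the TAIR10.1 assembly. Of 22746 probe sets without controls, 13513 named 1 gene, 503 named several and 8730 were not listed and stay unnamed here. Of the tested probe sets, 7718 named 1 gene, and 7693 of those matched a locus. No probe set naming several genes was given a gene name. Where a locus has a widely used symbol that the table lacks, both are given. No coordinates are printed, since the files name no genome build.

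The 64 control probe sets were left out, as were 8561 probe sets that did not reach a log2 value of 4 on at least 3 of the 12 arrays, which left 14185 tested. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with time as a factor of 4 levels, and variances were moderated with eBayes at its default settings (8 residual and 3.44 prior degrees of freedom). A moderated F-test asked whether the 4 means differed. The 3 degrees of freedom were also split into a 24-h harmonic (2 degrees of freedom) and a 12-h alternation, the mean of 6am and 6pm minus the mean of 12pm and 12am. All 6 differences between times were tested two-sided. P-values were adjusted by Benjamini-Hochberg over all tested probe sets within each test, and a call is an adjusted p below 0.05. Differences are on the log2 scale with the standard error of the model, levels are means with the standard deviation of 3 arrays. Where the lower mean was under a log2 of 4, the fold is given as a lower bound, with that mean set to 4, and the numbers of changes of at least 2-fold or 8-fold are counted in the same way. The minimum of 4 was chosen before the data were examined, and its use as a bound after. Genes were told apart by symbol. More than 1 tested probe set stood under 47 symbols, and the one with the highest mean over the 12 arrays stands for the gene. For 5 of these symbols, PWD among them, the probe sets name 2 loci, of which only the brighter one (AT5G26570 for PWD) was then used. The other probe set of AT5G54130 had a range of means of 4.40 against 4.35.

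The groups, tests, alternatives, 21 gene lists and the rule for named genes were fixed before the data were examined. The rule takes every tested member of the morning and evening clock lists. It takes the 10 largest computed rises and 10 largest falls between 6pm and 6am and between 12am and 12pm, and the 4 and 4 of each successive 6-h step, among called probe sets of 1 gene whose arrays do not overlap between the 2 times. It takes the 3 largest ranges per peak time, the 3 largest alternations each way, and up to 2 rises and 2 falls per list in the 2 opposite contrasts. List members named beyond this rule (COR47, ZAT10, SBE2.2, LHCB4.1, PRK, SEN5, PYK10) were chosen after their values were seen. Only 45 of the 350 list members were on a named probe set and 41 were tested, so 7 of 21 lists had the 3 members needed for a list test. Most core clock genes were among the members without a named probe set, and lists of heat shock, jasmonate, nitrogen and sulfur assimilation, and PIF and auxin growth genes had no tested member. Another 17 lists with 358 members were therefore drawn up from the names in the annotation table. These were chosen after the probe names and the overall numbers of calls had been seen, though before the value of any single gene was seen, and they are reported as added lists.

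Lists were tested with camera at a preset correlation between genes of 0.01, on 1 probe set per gene symbol, with adjustment over lists and the 2 opposite contrasts (14 tests for the fixed lists and 34 for the added ones). Camera with an estimated correlation and the directional fry test were run beside it. Fry asks whether a list moves one way on balance and does not compare it with other genes.

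The model was tested on simulated arrays with the measured means and spreads, in which 200 of 14185 probe sets were changed at 6pm. In the comparison of 6pm with 6am, 8% of changes of 0.5 log2, 62% of changes of 1, 96% of changes of 2 and all 50 changes of 3 were called, with 5 calls among unchanged probe sets. In this setting, changes well under 2-fold were often missed. The simulation changed few probe sets and held no replicate effect. In the data, 32.4% of tested probe sets were called between 6pm and 6am, with a median size of 0.915 log2. The adjustment is less strict when more probe sets change, so these recovered shares do not carry over to the data. In a simulation of 20 lists of independent genes, the 1 shifted list was called and no other. In the lists that camera called in the data, the estimated correlation between genes ran from 0.0366 (cell division) to 0.534 (starch synthesis). The simulation therefore cannot show how often correlated lists are called falsely.

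Alternatives covered the filter on dim probe sets, centring or quantile normalization of the deposited values, the variance model, array weights, a block for the replicate number, the choice of probe set, the threshold, only the 6 arrays of a comparison, and leaving out each array in turn. A term for replicate 1, a fit of replicates 2 and 3 only, and the added lists were chosen after seeing the data. Other splits of the arrays into groups were counted, as the closing part reports.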

Results

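Transcript levels were followed through one light and dark cycle in the shoots of Arabidopsis seedlings, with 3 arrays at each of 4 harvest times 6 h apart. The question of the comparison is which transcripts differ with the time of day. Within a time, replicates 2 and 3 correlated at 0.986 to 0.997 over the tested probe sets, and replicate 1 correlated with them at 0.967 to 0.984. The gap between the 3' and 5' probe sets of control genes, a measure of RNA integrity and labelling length, had a mean of 5.73 log2 on replicate 1 arrays against 4.72 on the others for actin, 2.21 against 1.89 for GAPDH and 3.27 against 3.14 for ubiquitin. Pooled over the 4 times, the ranges overlapped in all 3. For actin they overlapped only between 5.08 (12am replicate 1) and 5.09 (12am replicate 3). The median of 52 plastid-encoded transcripts was 8.48 to 9.66 log2 on replicate 1 arrays and 10.57 to 11.12 on the others. The number of arrays limits the precision of each value.

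The clock gene GIGANTEA (GI, AT1G22770) was at the lowest value of the table on all arrays at 6am and 12am, and reached 8.41 ± 0.37 at 12pm and 7.40 ± 0.28 at 6pm (SD, n = 3), at least 21.3-fold higher at 12pm. RVE6 (AT5G52660), a MYB-like transcription factor related to the morning clock genes, varied far less, from 7.56 ± 0.11 at 12pm to 5.97 ± 0.09 at 12am, a 3.01-fold range with an adjusted p of 8.85e-05 in limma's F-test. AT1G26790, which encodes a Dof-type transcription factor, was at 8.70 ± 0.15 at 6am and at the lowest value of the table at the other 3 times. Among probe sets naming 1 gene, the other widest computed ranges were in AT4G15430 and AT4G31875 with their highest mean at 6am, AT1G73480 and AT1G13650 at 12pm, AT4G30650, AT4G34950 and COR15B at 6pm, and XTH33, AT4G12500 and AT2G25990 at 12am. AT4G12500 varied widely at 12am, with 5.0 on replicate 1, 11.18 and 11.31 on replicates 2 and 3, and a mean of 9.16 ± 3.60.

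In all, 6639 of 14185 probe sets (46.8%) differed between the 4 times by limma's F-test, 3484 of them with a range of means of at least 2-fold and 330 with at least 8-fold once means under a log2 of 4 were set to 4. Of the 6639, 3471 named 1 gene. The highest mean was at 6am for 1989, at 12pm for 1801, at 6pm for 1432 and at 12am for 1417. With replicates 2 and 3 alone, 8279 probe sets were called.

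**Figure D1:**
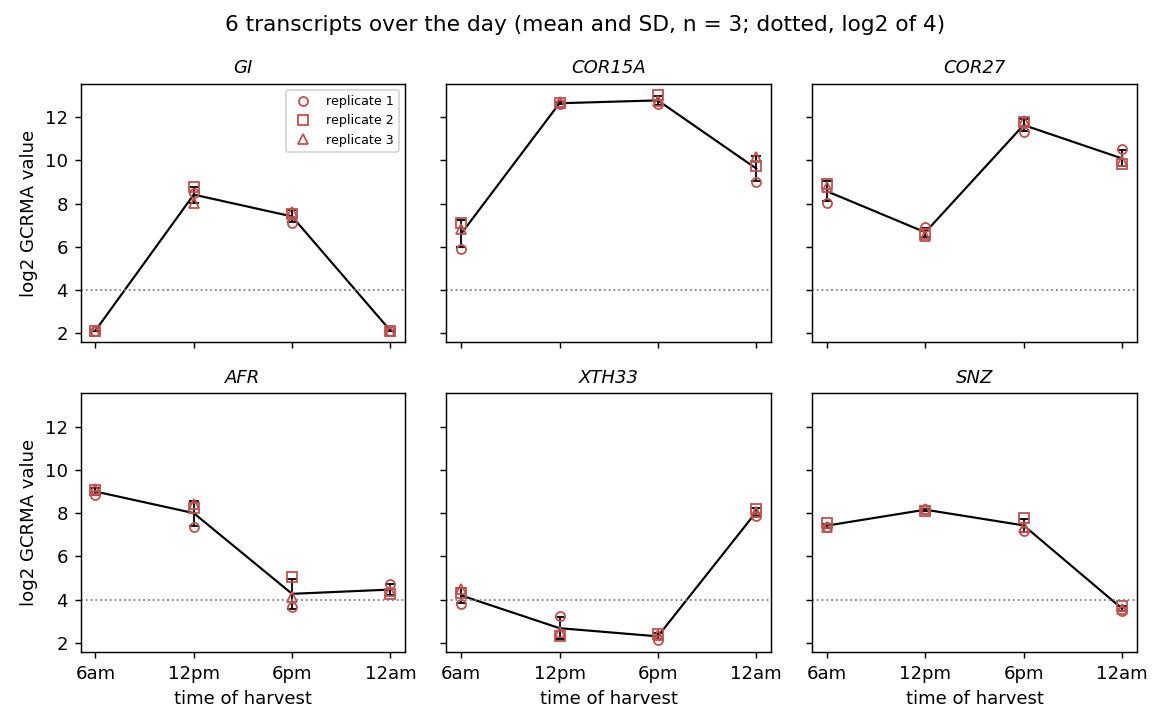
Log2 GCRMA values (vertical axis) of 6 transcripts at the 4 harvest times (horizontal axis). Open symbols are single arrays by replicate, lines join the means, bars are the SD of 3 arrays, and the dotted line is the log2 of 4 used as the filter's minimum. GI was at the lowest value of the table at 6am and 12am and at 8.41 at 12pm, while XTH33 reached 8.06 at 12am.

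COR15B (AT2G42530) and COR15A (AT2G42540), which encode chloroplast proteins that protect membranes during freezing, were higher at 6pm, 12 h into the light period, than at 6am by 6.29 ± 0.20 and 6.19 ± 0.32 on the log2 scale (SE), 78.3-fold and 72.9-fold, with every 6pm array above every 6am array. AT4G30650, of a family of small proteins responsive to low temperature and salt, rose by 7.11 on the log2 scale, or 138-fold, from a 6am mean of 5.40 ± 1.05, and by 90.8-fold without 6am replicate 1. Of the 4 tested cold-response genes, 3 rose, also 3 when adjusted over the list alone, with COR47 beside the COR15 pair, and the stress-related zinc-finger gene ZAT10 was at 3.91 at 6am and 5.14 at 6pm (adjusted p = 0.304). The list was higher by camera (adjusted p = 0.000404), and not with an estimated correlation between genes (adjusted p = 0.189). The other 6 lists had camera adjusted p from 0.196 to 0.985.

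Among probe sets naming 1 gene, other large rises from 6am to 6pm were in AT4G34950, of a family of membrane transporters (at least 67.4-fold), AT1G07050, a CCT-domain gene (at least 21.5-fold), AT5G62360, of the invertase and pectin methylesterase inhibitor family (at least 29.9-fold), and AT2G23910 (at least 23.5-fold). AT1G56300, a DnaJ-domain gene, rose 56.1-fold, AT4G16146 rose 47-fold and Fes1B, related to a binding partner of the chaperone Hsp70, rose 43-fold. Large falls among them were in AT4G15430 (at least 49-fold), AT1G26790 (at least 26-fold), AT4G31875 (at least 33.9-fold), the glutaredoxin-family gene AT1G64500 (42.2-fold) and AT2G15020 (at least 25.5-fold). AT2G41250 fell 32.9-fold, AFR, an F-box gene of phytochrome A signalling, fell 26.9-fold, and TRY, a small MYB repressor of leaf hair formation, fell 19.4-fold. AT1G65490 and AT5G54130 fell 22.2-fold and 20.3-fold, AT1G65490 by 36.1-fold without 6pm replicate 1. The largest computed rise and fall were both on probe sets that name no gene. HYH, a bZIP factor related to the light-signalling regulator HY5, was at 12.50 ± 0.01 at 6am and 8.73 ± 0.31 at 6pm, a fall of 13.6-fold.

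Both tested starch-degradation genes rose from 6am to 6pm: DPE1, the plastid disproportionating enzyme, by 2.99 ± 0.14, and PWD, a dikinase acting on phosphorylated starch, by 2.21 ± 0.13. APL3, a large subunit of ADP-glucose pyrophosphorylase, rose by 1.98 ± 0.21, and the other 2 starch-synthesis genes were not called. Of 5 chlorophyll-synthesis genes, PORB, a protochlorophyllide oxidoreductase, rose 2.32-fold, while CHLP (AT1G74470) fell by 1.02 ± 0.15 and CHLM by 0.39 ± 0.12. The CHLM call had an adjusted p of 0.0263 and was lost without 6am replicate 2 (0.0717), 6am replicate 3 (0.102) or 6pm replicate 2 (0.0851) and with only the 6 arrays of the 2 times (0.0854), with 0.00461 to 0.102 over its alternatives. Adjusted over the list alone, 2 chlorophyll genes rose and 2 fell, and for the other lists the counts in this comparison are the same either way. The chlorophyll list had a median of 0.34 and a mean of 0.11. Both glucosinolate genes, BCAT4 and UGT74B1, rose 2.15-fold and 1.78-fold. In the Calvin cycle RCA, the activase of Rubisco, fell by 0.57 ± 0.13 (adjusted p = 0.00642), and PRK and SBPASE were not called. LHCB4.2, an antenna protein of photosystem II, fell by 0.81 ± 0.12, with LHCB4.1 and LHCB4.3 not called, and that list had a median of 0.20, a mean of -0.05 and a downward but uncalled test. LYCB, the carotenoid enzyme listed as LYC, fell by 1.13 ± 0.23, CDF5 (AT1G69570), a Dof factor that represses flowering, by 0.91 ± 0.22, and the mitotic kinase gene AUR1 rose by 0.73 ± 0.15. Of 3 genes induced by sugar starvation, IVD and MCCA, enzymes of leucine breakdown, fell 2.69-fold and 2.3-fold, and SEN5 (AT3G15450) was not called. The IVD call (adjusted p = 0.0133) was lost without the filter on dim probe sets (0.0522, the highest of 0.000239 to 0.0522 over its alternatives). The MCCA call (adjusted p = 0.0343) was lost on leaving out any of the 6am or 6pm arrays: replicates 1, 2 and 3 of 6am (0.0964, 0.0614 and 0.0596) and of 6pm (0.0733, 0.0922 and 0.0599). It was also lost without the filter on dim probe sets (0.106). Its adjusted p ran from 0.000612 to 0.106 over its alternatives. By limma, 0 of 8 cytosolic ribosomal protein genes of the fixed list were called, and 0 at an unadjusted p below 0.05, and the root marker PYK10 was at 11.90 at 6am and 11.68 at 6pm (adjusted p = 0.404).

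Of all tested probe sets, 4596 differed between 6pm and 6am by limma's moderated test, 2362 higher and 2234 lower at 6pm, 990 and 946 of them by at least 2-fold with means under a log2 of 4 set to 4. With replicates 2 and 3 alone, 5570 were called, and 93.9% of those moved the same way in replicate 1.

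**Figure D2:**
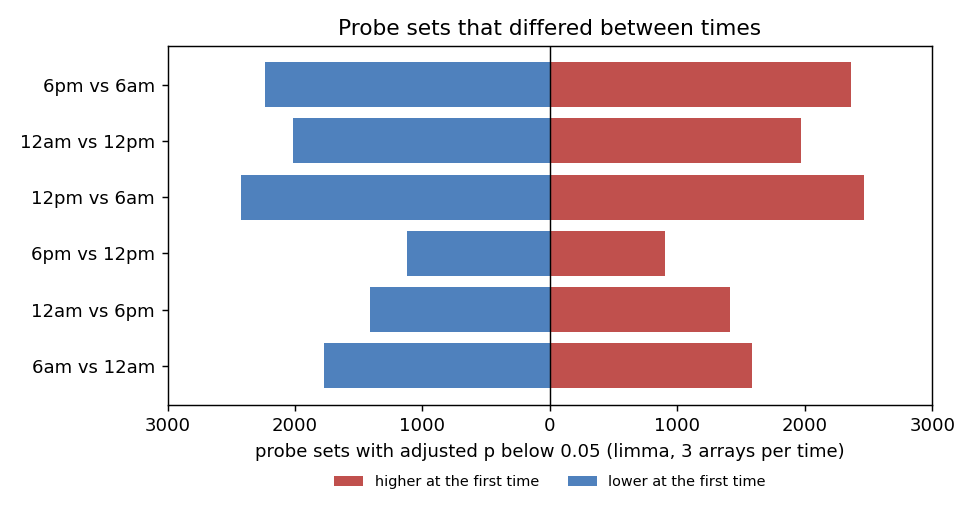
Numbers of probe sets with an adjusted p below 0.05 (horizontal axis) in each of the 6 comparisons of times (vertical axis), higher at the first-named time to the right and lower to the left. The comparison of 12pm with 6am gave 2461 higher and 2420 lower, and that of 6pm with 12pm gave 905 and 1119.

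XTH33, a xyloglucan endotransglucosylase that remodels cell walls, was at 8.06 ± 0.17 at 12am and 2.67 ± 0.50 at 12pm, at least 16.7-fold higher at midnight, and the expansin gene EXPA16 was at least 14.6-fold higher. GI was lower at midnight by at least 21.3-fold, and RVE6 fell by 1.59 ± 0.17. COR27, a cold- and clock-regulated gene, was higher at 12am than at 12pm by 3.43 ± 0.25, opposite to COR15A and COR15B, which were lower by 8.16-fold and 2.88-fold.

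Among probe sets naming 1 gene, the other large rises were in AT2G25990 (at least 12-fold), AT1G17665 (at least 8.21-fold), the small heat-shock-like gene AT4G21870 (13.8-fold), the transporter-family gene AT3G23550 (13-fold), AT5G28630 (at least 3.8-fold), AT1G10990 (at least 5.03-fold) and AT1G43910 (at least 5.62-fold, and 8.59-fold without 12am replicate 1). AT1G73480, of the alpha/beta hydrolase fold, fell from 10.32 ± 0.30 at 12pm to 2.56 ± 0.23 at 12am, at least 79.8-fold. The cytochrome P450 gene CYP71B26 fell 38.8-fold, the thionin gene THI2.2 fell 26.6-fold and SNZ, an AP2-type repressor of flowering, at least 18-fold. AT1G13650, AT3G46370 and AT1G57590 fell by at least 26.6-fold, 14.4-fold and 7.31-fold, AT4G13800 fell 29.2-fold and AT5G57340 fell 24-fold, or 36.3-fold without 12am replicate 1. The largest computed rise and fall were both on probe sets that name no gene.

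All 3 tested starch-synthesis genes were lower at midnight, also 3 when adjusted over the list alone: APL4 by at least 2.93-fold, APL3 by 2.38-fold and the branching enzyme SBE2.2 from 11.29 to 10.72 log2 (adjusted p = 0.0299). The list was lower by camera (adjusted p = 0.0133), and not with an estimated correlation (adjusted p = 0.323). The 5 lists besides these and the cold list had camera adjusted p from 0.123 to 0.725. Of the 4 cold-response genes 3 were lower, also 3 when adjusted over the list alone, with a camera adjusted p of 0.00778 and an adjusted p of 0.275 with an estimated correlation. BCAT4 and UGT74B1 fell by 2.54 ± 0.17 and 1.27 ± 0.17, PORB by 1.02, CHLP by 0.49 ± 0.15 and DPE1 by 1.37 ± 0.14. The CHLP fall was not called without 12pm replicate 2 or 3 or 12am replicate 2 or 3, with adjusted p of 0.0999, 0.0983, 0.0748 and 0.106, and from 0.000957 to 0.106 over its alternatives. LHCB4.3 rose 6.28-fold while LHCB4.2 fell 2.37-fold, so the light-harvesting list had a median of -0.24, a mean of 0.39 and no call. Adjusted over the list alone, LHCB4.1 was lower as well, and the counts of the other lists are the same either way. By limma 0 of 8 cytosolic ribosomal and 0 of 3 sugar-starvation genes of the fixed lists were called, with 1 and 0 at an unadjusted p below 0.05. HYH was 1.8-fold higher at midnight. DFR, an enzyme of anthocyanin synthesis, was at 7.56 ± 1.66 at 12am and 4.55 ± 0.31 at 12pm, an 8.05-fold rise with an adjusted p of 0.00336, and 15.7-fold without 12am replicate 1. In the Calvin cycle, SBPASE was higher by 0.41 ± 0.12 (adjusted p = 0.027), a call lost without 12pm replicate 1 (0.0881), 12pm replicate 2 (0.083), 12am replicate 2 (0.0945) or 12am replicate 3 (0.0619) and with replicates 2 and 3 alone (0.0634), with 0.00468 to 0.0945 over its alternatives.

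In all, 3987 probe sets differed between 12am and 12pm, 1970 higher and 2017 lower at midnight, 692 and 947 of them by at least 2-fold with means under a log2 of 4 set to 4. With replicates 2 and 3 alone, 5359 were called, and 91.8% of them moved the same way in replicate 1.

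The genes of the next comparisons had the largest computed changes among probe sets naming 1 gene, and where the fold is a bound their order is not known. From 6am to 12pm GI rose by at least 21.3-fold, COR15A by 66.5-fold, AT1G56300 by 58.9-fold and AT4G30650 by 55.4-fold (36.4-fold without 6am replicate 1), while AT1G26790 fell by at least 26-fold, AT4G15430 by 44.9-fold, the RING-finger gene AT1G49200 by 16.5-fold and AT5G54130 by 13.6-fold. From 12pm to 6pm AT1G07050 rose by at least 21.5-fold, COR27 by 31.5-fold, AT2G23910 by at least 23.5-fold and AT4G33980, the gene most closely related to COR27, by 17.9-fold. AT2G15020 and AT3G46370 fell by at least 17.5-fold and 14.4-fold, AT1G73480 by 24.4-fold and AT1G13650 by 23-fold. From 6pm to 12am XTH33, EXPA16 and DFR rose by at least 16.7-fold, 14.6-fold and 11.8-fold and the glutaredoxin-family gene AT1G06830 by 17.8-fold. Without 12am replicate 1 the DFR rise was at least 22.9-fold. GI, AT3G20340, AT1G51090 and AT1G57590 fell by at least 10.6-fold, 21.8-fold, 9.91-fold and 4.12-fold. From 12am to 6am AT1G26790 rose by at least 26-fold, AT2G41250 by 29.9-fold, AT4G31875 by 24.8-fold and AFR by 23.5-fold, while AT4G34950, AT5G62360 and AT2G23910 fell by at least 53.6-fold, 23.1-fold and 8.75-fold, AT5G62360 by at least 36.1-fold without 12am replicate 1. AT4G12500 fell by 4.88 ± 1.29 (adjusted p = 0.0181), and by 6.96 without 12am replicate 1. The call was lost without 12am replicate 2 (fall of 3.88, adjusted p = 0.082) or 12am replicate 3 (3.81, 0.0832). It was also lost without the filter on dim probe sets (0.0745) and with only the 6 arrays of the 2 times (0.0818), and over its alternatives the adjusted p ran from 1.15e-07 to 0.0832.

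The step from 6am to 12pm changed 4881 probe sets (2461 higher, 2420 lower at 12pm), that from 12pm to 6pm 2024 (905 higher, 1119 lower), that from 6pm to 12am 2826 (1412 higher, 1414 lower) and that from 12am to 6am 3363 (1587 higher, 1776 lower). By at least 2-fold, with means under a log2 of 4 set to 4, the higher and lower numbers were 1125 and 784, 225 and 575, 607 and 545, and 586 and 695 in that order. The count for 6pm against 12pm was 1313 without 12pm replicate 2 and 1340 without 12pm replicate 3, and that for 6am against 12am was 2126 and 2174 without 12am replicates 2 and 3. With replicates 2 and 3 alone the 4 counts were 6038, 2860, 3972 and 5111, of which 92.3%, 94.3%, 90.0% and 82.8% moved the same way in replicate 1. Successive steps share arrays, so their counts are not independent.

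A 24-h harmonic was called for 6349 probe sets, and among those called by the F-test a median of 88.3% of the variance between times lay in it. Patterns without a preferred shape would have a median of 75%, since the harmonic takes 2 of the 3 degrees of freedom. The fitted maximum fell most often 8 to 12 h after lights on (788 and 826 probe sets per 2 h) and 18 to 24 h after lights on (628, 754 and 683). A 12-h alternation was called for 1957, 875 higher at 6am and 6pm and 1082 higher at 12pm and 12am. Among probe sets naming 1 gene, those with the largest computed values toward 6am and 6pm were AT1G26790, COR27 (1.73 ± 0.18) and AT5G54130 (1.70 ± 0.10), and toward 12pm and 12am AT4G17470, DFR and AT2G47880. AT1G26790, AT4G17470, DFR and AT2G47880 had means under a log2 of 4, so the size and order of their alternation depend on where the floor lies and no value is given. AT1G26790 and AT5G54130 were called through a single high time, 6am. The alternation count was 1212 without 12am replicate 2, 1276 without 12am replicate 3 and 3437 with replicates 2 and 3 alone. Samples 6 h apart cannot resolve shorter rhythms.

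**Figure D3:**
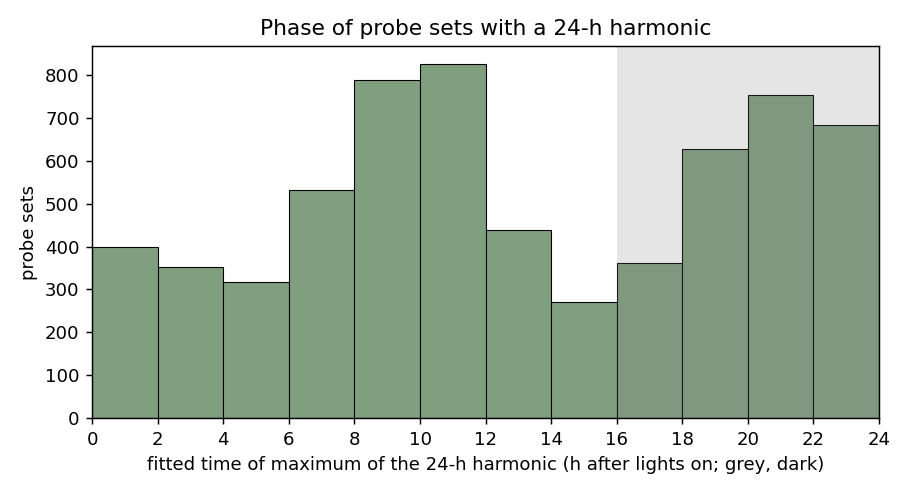
Number of probe sets (vertical axis) by the fitted time of the maximum of the 24-h harmonic in hours after lights on (horizontal axis, 2-h classes), for the 6349 probe sets with a called harmonic; grey marks the dark period. The classes from 10 to 12 h and from 20 to 22 h hold 826 and 754.

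**Figure D4:**
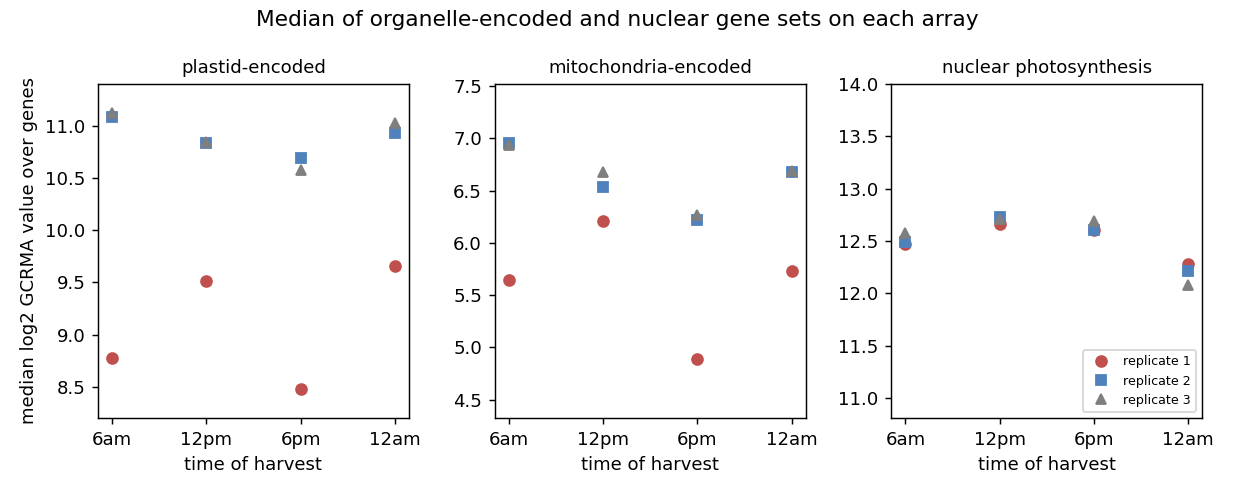
Median log2 GCRMA value (vertical axes, each spanning the same number of log2 units) of plastid-encoded, mitochondria-encoded and nuclear-encoded photosynthesis genes on each array, by harvest time (horizontal axis) and replicate (symbols). Plastid-encoded medians were 8.48 to 9.66 on replicate 1 arrays and 10.57 to 11.12 on the others, while the nuclear medians overlapped.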

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

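The term for replicate 1, the fit of replicates 2 and 3 alone and every test of the added lists were chosen after seeing the data. Of 3772 recomputed differences of named genes, 3657 kept their direction and side of the threshold, 115 kept the direction and lost the call, and 0 reversed by limma. These differences had been chosen as called on the same arrays, many of them as the largest, so none could gain a call. Most alternatives also reuse most of the arrays. Agreement was therefore likely in advance, and these numbers mainly show which calls were fragile. Centring the arrays on their medians, quantile normalization, trended and robust variances, no filter, a minimum of 6 and using only the 6 arrays of a comparison kept each count of probe sets within 1.5 times. Low signal over background limits genes near the lowest value, whose folds are bounds.

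Array weights raised the F-test count to 10304, the alternation to 4588, 12am against 12pm to 6492, 12pm against 6am to 7611, 6pm against 12pm to 3066, 12am against 6pm to 4666 and 6am against 12am to 7410, with peaks of 3133 at 6am, 2175 at 6pm and 2385 at 12am. A term for replicate 1 gave 8722 by the F-test, an alternation of 3469 and 3205 for 6pm against 12pm. Replicates 2 and 3 alone gave 3437 for the alternation and 5111 for 6am against 12am. For these alternatives the cause was not tested.

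The residuals of same-numbered arrays correlated at 0.0554 to 0.649, 17 of 18 pairs over 0.1. Those of arrays with different numbers correlated at -0.559 to 0.397, 5 of 36 pairs over 0.1, and 11 of the 12 arrays correlated best with one of their own number. Most of these values thus speak for a pairing by replicate number. As not every same-numbered pair passed, the number is not a block in the reported model. The pair that fell short was 6am and 12am of replicate 3 (0.0554). Differences shared by same-numbered arrays thus stay in the residual spread of the reported model, and a block takes them out. With the replicate number as a block the F-test called 8927, against 6639 in the reported model, and the harmonic 8350. The alternation was 3627, 6pm against 12pm 3303, 12am against 6pm 4313 and 6am against 12am 5111, and 2 added lists were called between 6pm and 6am. The F-test then called 7 of 52 plastid-encoded genes, against 0 in the reported model. How much of these rises comes from the smaller residual spread was not measured.

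The next counts are smaller by construction. With 1 probe set per gene symbol, 7671 were tested. The F-test then called 3423, the harmonic 3268 and the alternation 1006. The 6 comparisons gave 2330 for 6pm against 6am, 2037 for 12am against 12pm, 2537 for 12pm against 6am, 1001 for 6pm against 12pm, 1375 for 12am against 6pm and 1682 for 6am against 12am. Peaks were 1053, 926, 739 and 705 at 6am, 12pm, 6pm and 12am. At an adjusted p below 0.01 the F-test called 4424 and the alternation 753, the 6 comparisons in that order 2935, 2406, 3133, 1026, 1620 and 1807, and peaks were 1301 at 6am, 906 at 6pm and 944 at 12am. At an adjusted p below 0.05 with a computed change of at least 2-fold, the F-test called 3625, the harmonic 3534 and the alternation 280. The 6 comparisons gave 2031, 1716, 1997, 844, 1234 and 1357, and the peaks were 1028, 1146, 691 and 760.

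For the fixed lists, the main counts of 1 (6pm against 6am) and 2 (12am against 12pm) became 0 and 0 with an estimated correlation and 4 and 5 by fry, which asks another question. Without the filter 4 were called for 12am against 12pm, and replicates 2 and 3 alone gave 2 for 6pm against 6am. For the added lists, 1 and 1 became 0 and 0 with an estimated correlation and 6 and 9 by fry. Without the filter 3 were called for 12am against 12pm, and replicates 2 and 3 alone gave 4 and 2. The cause of these effects was not tested.

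Leaving out 1 array at a time gave 5723 to 7011 by the F-test, 5514 to 6786 for the harmonic and 1212 to 2522 for the alternation, which was 1276 without 12am replicate 3 and lowest without 12am replicate 2. It gave 3766 to 4821 for 6pm against 6am, 3005 to 4599 for 12am against 12pm, 3835 to 5102 for 12pm against 6am and 2056 to 3367 for 12am against 6pm. For 6pm against 12pm it gave 1313 to 2455, lowest without 12pm replicate 2 and 1340 without 12pm replicate 3. For 6am against 12am it gave 2126 to 3817, lowest without 12am replicate 2 and 2174 without 12am replicate 3. Peaks ran from 1651 to 2102 at 6am, 1469 to 1879 at 12pm, 1232 to 1545 at 6pm and 1107 to 1694 at 12am. Fixed lists stayed at 1 and 2 in number. Added lists ran from 1 to 3 for 6pm against 6am, highest without 6am replicate 1, and from 0 to 2 for 12am against 12pm, at 0 without 12pm replicate 1 and 2 without 12am replicate 1.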

Other observations

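The tests of 3' bias, of a shift of whole arrays and of RNA without a poly(A) tail, the regroupings within replicate numbers, and all comparisons of the added lists, were chosen after the results they concern had been seen.

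HTR12, the centromeric histone, rose from 6am to 6pm by 1.26 ± 0.16, POLA3, a subunit of DNA polymerase alpha and primase, by 0.99 ± 0.15, and AUR1 by 0.73 ± 0.15. Of 18 cell-division genes in the added list, 10 rose and 0 fell by limma, 11 and 0 when adjusted over the list alone, and 12 and 0 at an unadjusted p below 0.05. Camera called the list (adjusted p = 0.00156), and not with an estimated correlation (adjusted p = 0.3). It was the 1 added list called in this comparison, where 3 were called without 6am replicate 1. From 6am to 12pm 9 of the 18 genes were already higher and 0 lower, with a median of 0.816. From 12pm to 6pm 0 were called either way, with a median of -0.027. From 12am to 6am 8 were lower and 0 higher. The list was thus mainly low at 6am rather than high at 6pm alone.

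XTH33 and EXPA16 were at least 16.7-fold and 14.6-fold higher at 12am than at 12pm, while the expansin genes EXPB1 and EXPA8 were lower by at least 4.79-fold and by 4.31-fold. Of 15 cell wall genes 7 were higher and 4 lower, with no list call (camera adjusted p = 0.288). The ribosomal protein gene AT2G39390 was higher at 12am by 0.70 ± 0.12, and 9 of 64 cytosolic ribosomal protein genes were higher and 0 lower, with 18 and 0 at an unadjusted p below 0.05. Of all 14185 tested probe sets, 1970 were called higher and 2017 lower. The share called higher is thus near that of all probe sets, while 0 were lower in the list. That list was called by camera (adjusted p = 0.00156), and not with an estimated correlation (adjusted p = 0.784). It was the 1 added list called in this comparison, with 0 called without 12pm replicate 1 and 2 without 12am replicate 1. The remaining added lists had camera adjusted p from 0.336 to 0.965 between 6pm and 6am and from 0.151 to 0.937 between 12am and 12pm.

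Replicate 1 arrays correlated less with replicates 2 and 3 than those did with each other at every time. A harvest of replicate 1 shifted in one direction at every time is argued against as the main cause. The deviation of replicate 1 from the others reached an absolute correlation of 0.3 with the slope of the 24-h harmonic at 0 of 4 times, across 7801 probe sets that are not independent. At 12am the correlation was 0.207, which corresponds to 0.836 h and 4.28% of the variance, against -0.0671 to 0.0248 at the other times. A fitted shift of 0.836 h thus stays under the limit of 0.3, so the test cannot exclude shifts of that size. A small shift of the 12am array stays open. More 3' bias stays open: the actin 3' minus 5' difference was highest on replicate 1 at 3 of 4 times, with 12am replicate 3 as the exception. The GAPDH difference was highest on replicate 1 at 6am, 12pm and 6pm, and the ubiquitin difference only at 6am and 12pm. Bright probe sets of replicate 1 differed more from both others than those did from each other at 3 of 4 times. Their median differences were 0.314 and 0.319 against 0.0876 at 6am, 0.212 and 0.191 against 0.147 at 12pm, and 0.220 and 0.240 against 0.126 at 12am. Noise of dim probe sets as the only cause is argued against at these 3 times. At 6pm it stays open, with 0.262 and 0.193 against 0.198. No biological explanation was tested, since the labels give replicate 1 no group of its own.

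Plastid-encoded transcripts were lower on replicate 1 arrays, whose medians were 8.48 to 9.66 against 10.57 to 11.12 over 52 genes. Less green tissue is argued against, as nuclear-encoded photosynthesis genes deviated by a median no lower than -0.0468 at any time. The array medians differed by at most 0.0296 but cannot test a shift of whole arrays, since normalization between arrays fixes them. A uniform shift would move all genes alike. Over the 4 times, plastid-encoded genes deviated by medians of -1.82 to -0.875 and nuclear-encoded photosynthesis genes by -0.0468 to -0.0151. These values argue against a uniform shift of the replicate 1 arrays as the source. Less RNA without a poly(A) tail in the labelled material is consistent with the mitochondria-encoded median being lowest on replicate 1 at 4 of 4 times, a candidate explanation that was found on the same arrays. With all 12 arrays limma's F-test called 0 of 52 plastid-encoded genes, and 0 at an unadjusted p below 0.05. It called 21 with replicates 2 and 3 alone, 18 of them highest at 6am, and 10 with a term for replicate 1, 6 of them highest at 6am, so the number depends on the model. On replicate 1 arrays the plastid-encoded median was 8.78 at 6am, below 9.51 at 12pm and 9.66 at 12am, so a high at 6am is not seen there. The lowest time was shared: in each replicate the plastid-encoded median was lowest at 6pm (8.48, 10.69 and 10.57 in replicates 1, 2 and 3). So was the mitochondria-encoded median (4.89, 6.22 and 6.26). Of the 21 genes called with replicates 2 and 3 alone, 10 were lowest at 6pm.

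By the F-test 16 of 64 cytosolic ribosomal protein genes were called, against 46.8% of all tested probe sets, and 15 of the 16 were highest at 6am, with a median range of 0.64. From 6am to 12pm, 22 of the 64 were lower and 0 higher, against 2420 lower and 2461 higher of all 14185 tested. Over the 64 genes the median of 12pm minus 6am was -0.318, that of 6pm minus 6am -0.062 and that of 6am minus 12am 0.119. The list was thus mainly low at 12pm, and 6am was little above 6pm and 12am. Whether the replicate 1 arrays are the source stays open: 14 of the 16 were highest at 6am within replicates 2 and 3, and 10 within replicate 1 alone, but the 16 had been called on all of these arrays, so the test had little chance to come out otherwise. Probe sets shared between paralogs stay open: all 16 probe sets lacked the suffix that marks shared probes, but only 0.428% of tested probe sets of 1 gene carry it, so that test is weak as well. Time is the factor by which these genes were called, and no other group of the design bears on the pattern.

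Regrouping the 12 arrays asked whether chance can be excluded. The real split was the only 1 of 100 to reach 6639 by the F-test (highest other 1743), 6349 for the harmonic (1154) and 1957 for the alternation (1580). Chance can thus be excluded for the F-test count among regroupings that ignore the replicate number. Every other split mixed arrays of different times, which puts real differences between times into the residual spread. For the harmonic and the alternation the splits therefore ask whether times differ at all. They cannot tell whether a 24-h or 12-h shape is present, so no conclusion is drawn for these shapes. Among 100 splits with 1 array of each replicate number at each time, the real one was again the only 1 to reach its count by the F-test (highest other 3685) and for the harmonic (3924). For the alternation 2 of 100 did, a share still under 0.05, but the other split gave 2973 and thus more than the real one. The limit on the shapes holds for these splits too. For comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. Every other split also mixes the 2 times in both groups. Their difference then enters the residual spread, so low counts of probe sets in the other splits are largely built in. The real split gave 4596 for 6pm against 6am, 3987 for 12am against 12pm, 4881 for 12pm against 6am and 2826 for 12am against 6pm, each with 0 as the highest other and 1 of 10 splits as large. It gave 2024 for 6pm against 12pm (highest other 1) and 3363 for 6am against 12am (highest other 12), again 1 of 10. For the fixed lists, 7 of 10 splits gave as many as the real 1 for 6pm against 6am (highest other 2), and 4 of 10 as many as the real 2 for 12am against 12pm (highest other 3).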
